A study of Homo sapiens with 328 samples.

How the data were processed

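Gene expression was measured in 328 libraries with TempO-Seq, a targeted assay in which pairs of detector oligonucleotides anneal side by side on an mRNA, are ligated and are then amplified with barcoded primers, so that each read counts 1 ligated probe. The human whole transcriptome panel was used on lysates of cells exposed for 6 hours to a chemical or to the solvent dimethyl sulfoxide (DMSO, vehicle). The deposited table held whole-number counts per probe, with no normalization, for 22533 probes that carried 19641 gene symbols, and 2204 symbols had more than 1 probe. Reads were aligned to the probes with Bowtie, per the submitters' processing notes; its version, the genome build and the annotation were not given in the sources used here, so no coordinates are printed. A probe is named by its gene symbol as in the deposited table.

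Libraries were assigned to 4 cell types, 6 chemicals, 3 dose codes and 2 plates from the labels. Each dose group had 4 libraries and each plate had 5 vehicle libraries per cell type. The design text names concentrations of 10, 100 and 1000 micromolar in 0.1% DMSO, but no label ties a code (D1, D2 or D3) to a concentration, so codes are used as names only and no order of dose is read from them. The design text states that each condition was run in 4 biological replicates; the labels give no culture, passage or day for a library, so p-values measure the spread between these libraries. Replicate numbers follow the order of the records and only name a library. The positive control of each plate, trichostatin A, was not analysed here.

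XIST and genes of the Y chromosome (51 probes) were left out of every step, which left 22482 probes. Totals ran from 115156 to 8100142 counts (median 4784726); no library fell under the minimum of 100000 counts and 1 lay under 500000. PCR reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only. Among 512 pairs of libraries of 1 group none held identical counts, and the lowest chi-square per degree of freedom was 1.32 over probes with at least 10 counts in the pair, so each library counted as 1 sample.

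Probes were kept per cell type with edgeR's filterByExpr over the groups of that cell type, which left 13549 probes in A549, 13016 in HepG2, 14366 in the cardiomyocytes and 13918 in MCF7; 11118 probes passed in all 4. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment over the probes of a contrast at 0.05. Each chemical was fitted with its 3 codes and the vehicle libraries of its own plate (17 libraries). Avobenzone was tested at each code; each comparator was tested jointly over its 3 codes, with counts per code as the breakdown. The hydroxybenzophenone isomers were compared pairwise at matched codes in 1 fit per cell type (41 libraries). Kaempferol and myricetin, which lay on different plates, were compared as a difference of differences from the vehicle of each plate (34 libraries). Avobenzone's effect was compared between cell types by an F test of the interaction terms (68 libraries), and the vehicle libraries of both plates were compared within each cell type (10 libraries). Isomer comparisons used no vehicle library in the difference. No overlap between chemicals that share vehicle libraries is reported.

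A gene list was tested with camera of limma at a preset correlation of 0.01, adjusted over the lists with at least 3 measured genes within a contrast, and again with the correlation estimated per list; fry was run beside it. The 35 lists (490 members) and 40 genes of special interest were fixed before the data were examined, as were the groups, the designs, the rule for named genes and all alternatives except those said to be chosen after seeing the data. A gene with several probes counts through the probe of highest mean count. The rule names, per cell type and code of avobenzone, the 3 probes with the largest rise and the 3 with the largest fall among those past 0.05 with a mean of at least 5 library-scaled counts (CPM) and no overlap between the 4 treated and 5 vehicle libraries. It takes 2 and 2 probes for a comparator or a pair of compounds, at the code with the most calls. For each list described it adds up to 4 members with the largest change past the threshold, and it adds the 40 fixed genes. CPM values use the raw totals, and a prior count of 2 entered log2 CPM only. A fold against a group with 0 counts was set against a floor of 3 counts over the group, and a fold against 1 to 3 counts is given as a ratio with its exact 95% counting interval. The response share of a library is the slope of its log2 CPM, less the mean of its vehicle libraries, on the fitted D1 fold changes of the probes called at D1, in percent, given where D1 had at least 100 calls. Totals of each dose group were compared with their vehicle libraries by an exact 2-sided permutation test.

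Avobenzone fits were checked on probes simulated independently from totals and vehicle means (200 changed, at least 5 CPM). In A549, HepG2, cardiomyocytes and MCF7, 58%, 78%, 60% and 77% of 100 were called at a log2 change of 1. At 2, 99%, 99%, 98% and 100% were, with 7, 6, 4 and 4 false calls. Unchanged codes gave 0, but regrouped real cardiomyocyte D3 and vehicle libraries up to 5929.

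The alternatives were DESeq2's size factors in the same fit, no count filter, DESeq2 1.42.0 in place of edgeR, counts summed per symbol, a minimum of 500000 counts per library, fits of the compared groups only or of all groups of a plate, and leaving out each library in turn. Added after seeing the data were fits without the libraries that stand apart, defined as a correlation of log2 CPM under 0.9 with the mean of the rest of their group, cell types compared without 1 well, cell types and plates with the well as a block, and plates with leading axes of spread as covariates. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.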

Results

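RNA of 4 human cell types was counted after 6 hours with 1 of 6 chemicals or with solvent. The cells were A549 (a lung epithelial carcinoma line), HepG2 (a hepatocellular carcinoma line), cardiomyocytes derived from induced pluripotent stem cells, and MCF7 (a breast adenocarcinoma line). Avobenzone, an organic ultraviolet filter of sunscreens, is the chemical named in the series title. It was set beside 2-, 3- and 4-hydroxybenzophenone, isomers that differ in the position of a hydroxyl group, and beside the flavonols kaempferol and myricetin. Each chemical was used at 3 dose codes, D1, D2 and D3, with 4 libraries per code, and 5 vehicle libraries stood on each of 2 plates per cell type. Plate 10 held avobenzone, the hydroxybenzophenones and kaempferol, and plate 11 held myricetin. Values in parentheses after a gene are log2 fold changes ± SE of 4 treated against 5 vehicle libraries of the same plate. Adjusted p-values are those of edgeR's quasi-likelihood test or, for gene lists, of camera. For a list, the genes past the threshold are counted among those measured, and where no second count follows, the count adjusted over the list alone was the same.

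Total counts per library ran from 2794432 to 5616100 in A549 and from 1877876 to 7996915 in HepG2. They ran from 115156 to 7988646 in the cardiomyocytes and from 2535331 to 8100142 in MCF7, with 82 libraries per cell type. No dose group passed the threshold for total counts in 72 exact permutation tests (smallest adjusted p = 0.648), but with a smallest possible p of 0.00794 for 4 against 5 libraries a single group could not have passed, so equal totals were not shown. Of 328 libraries, 4 correlated with the rest of their group below 0.9. They were the cardiomyocyte libraries 2-hydroxybenzophenone D3 replicate 1 (0.863) and plate 11 vehicle replicate 5 (0.805). In MCF7 they were 2-hydroxybenzophenone D1 replicate 4 (0.748) and kaempferol D1 replicate 3 (0.87). Probe sequences were not used here, so near-identical genes such as HSPA1A and HSPA1B, the metallothioneins or the clustered histone genes could not be told apart.

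**Figure D1:**
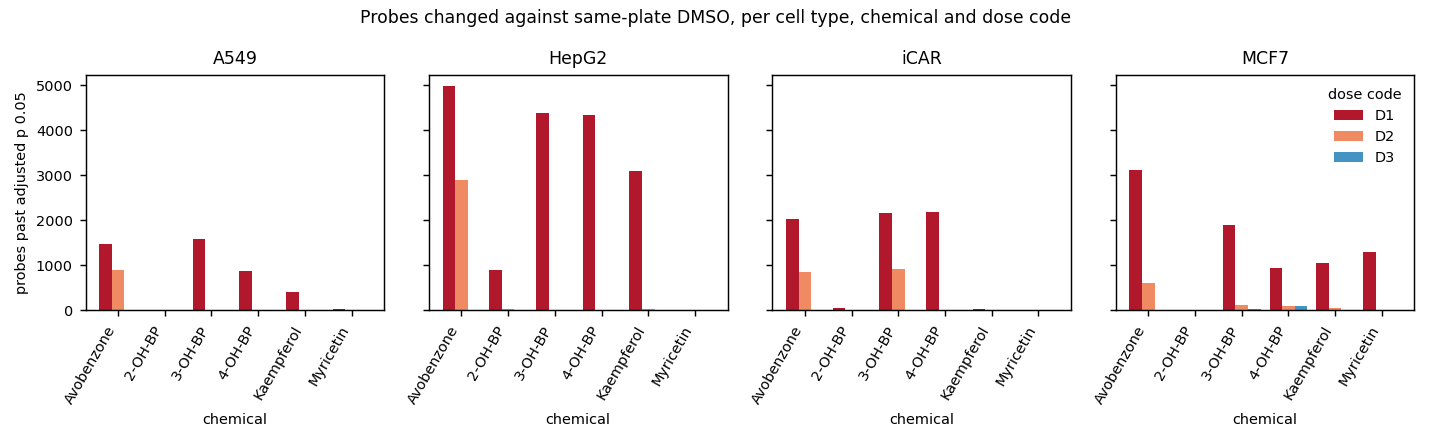
Number of probes past an adjusted p of 0.05 (edgeR, 4 treated against 5 vehicle libraries) for each chemical (x axis), dose code (colour) and cell type (panel; OH-BP, hydroxybenzophenone; iCAR, cardiomyocytes). Avobenzone D1 changed 1473 probes in A549, 4992 in HepG2, 2023 in the cardiomyocytes and 3116 in MCF7, and its D3 changed 0 in each.

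In A549, avobenzone D1 raised genes of the integrated stress response, of hypoxia and of the early growth response, and lowered heat shock genes. The integrated stress response, the program of ATF4 and its targets, rose in 15 of 20 genes (19 adjusted over the list alone), led by DDIT3 (3.52 ± 0.2), SESN2 (3.25 ± 0.34), STC2 (3.2 ± 0.49) and TRIB3 (3.19 ± 0.18). Hypoxia genes rose in 14 of 17 genes. Among them hexokinase 2, HK2 (4.74 ± 0.3), went from 2.76 ± 1.33 (SD, n = 5) to 68 ± 13.1 CPM (SD, n = 4). The pH regulator CA9 (3.02 ± 0.47) and the oxygen sensor EGLN3 (2.76 ± 0.18) rose too. Immediate early genes rose in 12 of 16 genes (13 adjusted over the list alone), with EGR1 (4.07 ± 0.65) and FOSB (3.88 ± 0.73). The orphan receptor NR4A1 was at least 11.1-fold higher, from 0 to 30 counts. Inflammatory genes of NF-kB rose in 9 of 16 genes (10 adjusted over the list alone), including the neutrophil attractant CXCL8 (3.03 ± 0.24). The chemokine CCL20 was higher by 78.1-fold, 95% counting interval 21.2 to 651. Heat shock genes fell in 10 of 15 genes (11 adjusted over the list alone), led by the inducible chaperones HSPA1B (-3.38 ± 0.23) and HSPA1A (-2.94 ± 0.65) and the co-chaperone DNAJA1 (-1.75 ± 0.23).

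The dioxin-responsive monooxygenases CYP1B1 (-2.29 ± 0.3) and CYP1A1 (-2.25 ± 0.54) fell in A549 at D1, and the amino acid transporter subunit SLC7A9 (-3.07 ± 0.65) fell as well. Cholesterol synthesis genes fell in 4 of 22 genes (5 adjusted over the list alone), with INSIG1 (-1.4 ± 0.22), LDLR (-1.26 ± 0.2) and IDI1 (-1.24 ± 0.12). That call was lost with adjusted p = 0.0659 with an estimated correlation. The AhR list fell in 3 of 9 genes and the mitosis list in 6 of 15 genes (10 adjusted over the list alone). These had adjusted p = 0.0701 and adjusted p = 0.149 with an estimated correlation. The lists of the integrated stress response (adjusted p = 1.37e-46), hypoxia (1.46e-41), immediate early genes (3.94e-28), NF-kB (1.22e-13) and heat shock (5.69e-13) held with it. At D2 the integrated stress response rose in 16 of 20 genes (18 adjusted over the list alone), with SESN2 (3.46 ± 0.34) and ATF3 (3.18 ± 0.69). Hypoxia genes rose in 13 of 17 genes (15 adjusted over the list alone) (HK2 (4.04 ± 0.3)), and heat shock genes fell in 8 of 15 genes (9 adjusted over the list alone) (HSPA1B (-2.86 ± 0.22)). At D2 CEP295NL (-3.42 ± 0.95) and the HSP90 co-chaperone FKBP4 (-3.04 ± 0.71) fell.

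The counts in A549 were 711 higher and 762 lower probes of 13549 at D1, and 448 and 462 at D2. Code D3 gave 0 calls by edgeR, with 260 probes at an unadjusted p under 0.05, and 0 by DESeq2. Leaving out 1 library gave 917 to 950 without avobenzone D1 replicate 1 or 3 at D1. At D2 it gave 474 to 508 without vehicle replicate 2 or avobenzone D2 replicate 1, 2 or 3. Fitting all groups of the plate together gave 2313 and 1606 calls at D1 and D2.

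In HepG2, avobenzone D1 changed more probes than in any other cell type, 2777 higher and 2215 lower of 13016. Immediate early genes rose in 20 of 20 genes, hypoxia genes in 16 of 17 genes and inflammatory genes of NF-kB in 9 of 13 genes (10 adjusted over the list alone). They had adjusted p = 0.147, 0.147 and 0.148 with an estimated correlation, in that order. The AP-1 subunit FOSB (7.68 ± 0.75) and the transcription factor EGR1 (5.83 ± 0.64) rose, and FOS was higher by 122-fold, 95% counting interval 41.4 to 597, with 3 vehicle counts. Of the hypoxia genes the glycolytic regulator PFKFB3 (4.92 ± 0.52), NDRG1 (4.27 ± 0.47) and the vasodilator peptide ADM (3.64 ± 0.44) rose most. The chemokines CXCL2 (5.08 ± 0.41), CXCL8 (5.05 ± 0.51) and CXCL1 (4.41 ± 0.52) led the NF-kB genes. Metallothioneins, which bind zinc and copper, rose in 7 of 8 genes (MT2A (1.65 ± 0.37)), and the bile acid list in 4 of 6 genes. Both had adjusted p = 0.147 with an estimated correlation. Bile acid genes that rose were the exporter subunit SLC51A (2.5 ± 0.42), the synthesis enzyme CYP7A1 (2.29 ± 0.5) and its repressor NR0B2 (1.87 ± 0.21). The apoptosis regulator MCL1 (3.58 ± 0.44) rose too.

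Genes of mitosis fell in HepG2 at D1 in 12 of 15 genes (13 adjusted over the list alone) and genes of DNA replication in 10 of 19 genes. These had adjusted p = 0.218 and adjusted p = 0.147 with an estimated correlation. Cyclin B1, CCNB1 (-1.22 ± 0.2), the kinase PLK1 (-1.2 ± 0.27) and the sliding clamp PCNA (-1.42 ± 0.33) were among them. The largest falls that the rule named were those of the histone gene H3C13 (-3.0 ± 0.34), of FAM227A (-3.0 ± 0.72) and of MFAP3L (-2.93 ± 0.67).

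Code D2 in HepG2 raised 1831 and lowered 1061 probes. The adhesion protein TNS1 (4.68 ± 0.61), the MAP kinase phosphatase DUSP5 (4.11 ± 0.49) and CXCL8 (4.0 ± 0.49) rose. The histone genes H2BC6 (-2.03 ± 0.51) and H3C13 (-1.95 ± 0.32) and the cell cycle inhibitor CDKN2C (-2.0 ± 0.31) fell. Immediate early genes rose in 18 of 20 genes (19 adjusted over the list alone) and hypoxia genes in 15 of 17 genes, and mitosis genes fell in 12 of 15 genes (15 adjusted over the list alone). Each had adjusted p = 0.13 with an estimated correlation. Targets of the oxidative stress factor NRF2 rose in 7 of 19 genes (GCLC (2.18 ± 0.33), SRXN1 (1.26 ± 0.21)), with adjusted p = 0.274 with an estimated correlation. Code D3 gave 0 calls by edgeR, 90 probes at an unadjusted p under 0.05 and 0 by DESeq2. At D2 replicate 4, from well H01, showed 11% of the D1 response, against 73% ± 5.51 (SD, n = 3) in the others. The D2 count was 1606 without avobenzone D2 replicate 3 and 4552 without avobenzone D2 replicate 4.

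In the cardiomyocytes, avobenzone D1 raised immediate early genes in 15 of 19 genes, with FOS (5.07 ± 0.56), NR4A1 (4.8 ± 0.58) and FOSB (4.33 ± 0.76). The related orphan receptor NR4A3 (5.18 ± 0.51) rose most of all named probes. Chaperones of the endoplasmic reticulum (ER) rose in 8 of 16 genes (11 adjusted over the list alone), the integrated stress response in 8 of 20 genes (10 adjusted over the list alone) and cholesterol synthesis in 11 of 21 genes (16 adjusted over the list alone). These list calls were lost, with adjusted p = 0.273, 0.335 and 0.327, with an estimated correlation. The ER genes HERPUD1 (3.56 ± 0.47), PDIA4 (2.94 ± 0.64) and HSPA5 (2.25 ± 0.3) and the stress factors DDIT3 (5.09 ± 0.61) and ATF3 (2.95 ± 0.56) rose. So did INSIG1 (2.6 ± 0.44), the synthase HMGCS1 (1.68 ± 0.33) and IDI1 (1.63 ± 0.3). Hypoxia genes rose in 5 of 16 genes (6 adjusted over the list alone) and p53 targets in 6 of 20 genes (7 adjusted over the list alone). These had adjusted p = 0.629 and 0.273 with an estimated correlation. ADM (2.0 ± 0.37), VEGFA (1.83 ± 0.35) and the stress cytokine GDF15 (3.0 ± 0.45) were among them. The rule named falls of TMED6 (-5.27 ± 1.03), the synuclein SNCG (-3.45 ± 0.69) and the antiproliferative factor BTG1 (-3.07 ± 0.48).

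At D2 in cardiomyocytes NR4A3 (4.91 ± 0.51), the macrophage growth factor CSF1 (4.54 ± 0.61) and RASD1 (3.55 ± 0.46) rose, and SNCG (-3.92 ± 0.72), TDRD6 (-2.4 ± 0.59) and PRR16 (-1.62 ± 0.42) fell. Cholesterol synthesis rose in 13 of 21 genes (16 adjusted over the list alone) (INSIG1 (2.89 ± 0.44)), with adjusted p = 0.0963 with an estimated correlation. The immediate early list held at both codes with an estimated correlation (adjusted p = 0.0112 at D1). The counts were 1039 higher and 984 lower of 14366 at D1, and 635 and 215 at D2. Code D3 gave 0 calls by edgeR, 1376 probes at an unadjusted p under 0.05 and 2 by DESeq2. Without single libraries the count was 1257 to 1313 without vehicle replicate 4 or avobenzone D1 replicate 1 or 3 at D1. At D2 it was 338 to 537 without vehicle replicate 2 or 4 or avobenzone D2 replicate 1, 2 or 3 and 1970 without avobenzone D2 replicate 4. Replicate 4 of D2, from well H01, showed 30.8% of the D1 response, against 61.3% ± 5.15 (SD, n = 3) in the others.

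In MCF7, avobenzone D1 raised hypoxia genes in 17 of 17 genes, with NDRG1 (4.57 ± 0.54) and CA9 (3.61 ± 0.74). The integrated stress response rose in 19 of 20 genes. Among these were ATF3 (3.66 ± 0.44), the glutathione-degrading enzyme CHAC1 (3.28 ± 0.42), DDIT3 (3.09 ± 0.34) and asparagine synthetase, ASNS (2.82 ± 0.3). Inflammatory genes of NF-kB rose in 12 of 13 genes, with CXCL8 (6.17 ± 0.63), the largest rise that the rule named. Immediate early genes rose in 17 of 19 genes (EGR2 (3.25 ± 0.49)). NRF2 targets rose in 7 of 20 genes (11 adjusted over the list alone), with the cystine transporter SLC7A11 (3.06 ± 0.42), and metallothioneins in 3 of 3 genes (MT2A (2.37 ± 0.58)). Cholesterol synthesis fell in 17 of 21 genes (18 adjusted over the list alone), with INSIG1 (-1.73 ± 0.16), mevalonate kinase, MVK (-1.71 ± 0.27), and HMGCS1 (-1.25 ± 0.17). Genes of DNA replication fell in 14 of 18 genes (15 adjusted over the list alone), with cyclin E1, CCNE1 (-1.77 ± 0.32). Mitosis genes fell in 11 of 15 genes (14 adjusted over the list alone) (AURKA (-1.11 ± 0.13)) and lipogenesis genes in 5 of 14 genes (7 adjusted over the list alone) (the elongase ELOVL6 (-1.54 ± 0.27)). The scaffold AKAP12 (6.02 ± 0.57) and the homeobox gene HOXB9 (5.05 ± 0.6) also rose. The histone genes H2AC4 (-2.98 ± 0.32) and H3C12 (-2.53 ± 0.23) and the transcription factor SOX2 (-2.93 ± 0.31) fell.

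At D2 in MCF7 hypoxia genes rose in 16 of 17 genes (17 adjusted over the list alone) and the integrated stress response in 16 of 20 genes (19 adjusted over the list alone) (CHAC1 (2.98 ± 0.42)). Cholesterol synthesis fell in 12 of 21 genes (18 adjusted over the list alone) (MVK (-1.71 ± 0.27), INSIG1 (-1.32 ± 0.16)). The transcription factor MAFF (2.86 ± 0.42) and PPFIA4 (3.92 ± 0.48) rose, and SOX21 (-1.43 ± 0.37) fell. Every list of MCF7 named so far held with an estimated correlation at its code. At D3 cholesterol synthesis was lower as a list (median -0.26, 1 member adjusted over the list alone; adjusted p = 3.47e-23 by camera). AhR targets were higher (median 0.25, 3 of 9 adjusted over the list alone; adjusted p = 4.34e-09). Both D3 lists had adjusted p = 2.61e-04 with an estimated correlation. The counts were 1634 higher and 1482 lower of 13918 at D1, and 471 and 133 at D2. Code D3 gave 0 calls by edgeR, 115 probes at an unadjusted p under 0.05 and 1 by DESeq2. Leaving out 1 library gave 303 to 400 without vehicle replicate 2, 4 or 5 or avobenzone D2 replicate 1, 2 or 3 and 1294 without avobenzone D2 replicate 4 at D2. There replicate 4, from well H01, showed 13.5% of the D1 response, against 60.6% ± 2.27 (SD, n = 3) in the others.

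**Figure D2:**
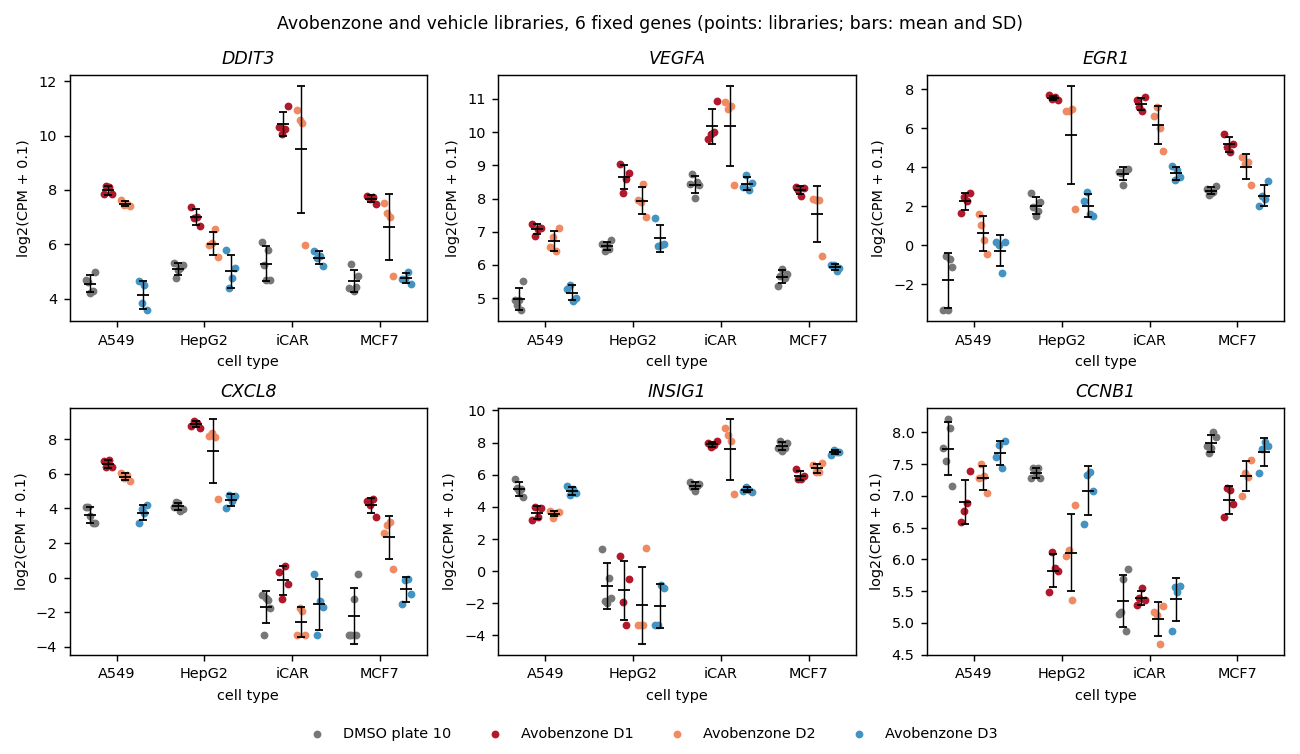
Log2 of CPM plus 0.1 (y axis) of 6 fixed genes in the avobenzone and plate 10 vehicle libraries (points), by cell type (x axis) and group (colour), with mean and SD as bars (n = 5 vehicle libraries, 4 per code). DDIT3 rose at D1 by 3.52 in A549, 2.23 in HepG2, 5.09 in the cardiomyocytes (iCAR) and 3.09 in MCF7, on the log2 scale of the fit, and points on a common lowest value are libraries with 0 counts.

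**Figure D3:**
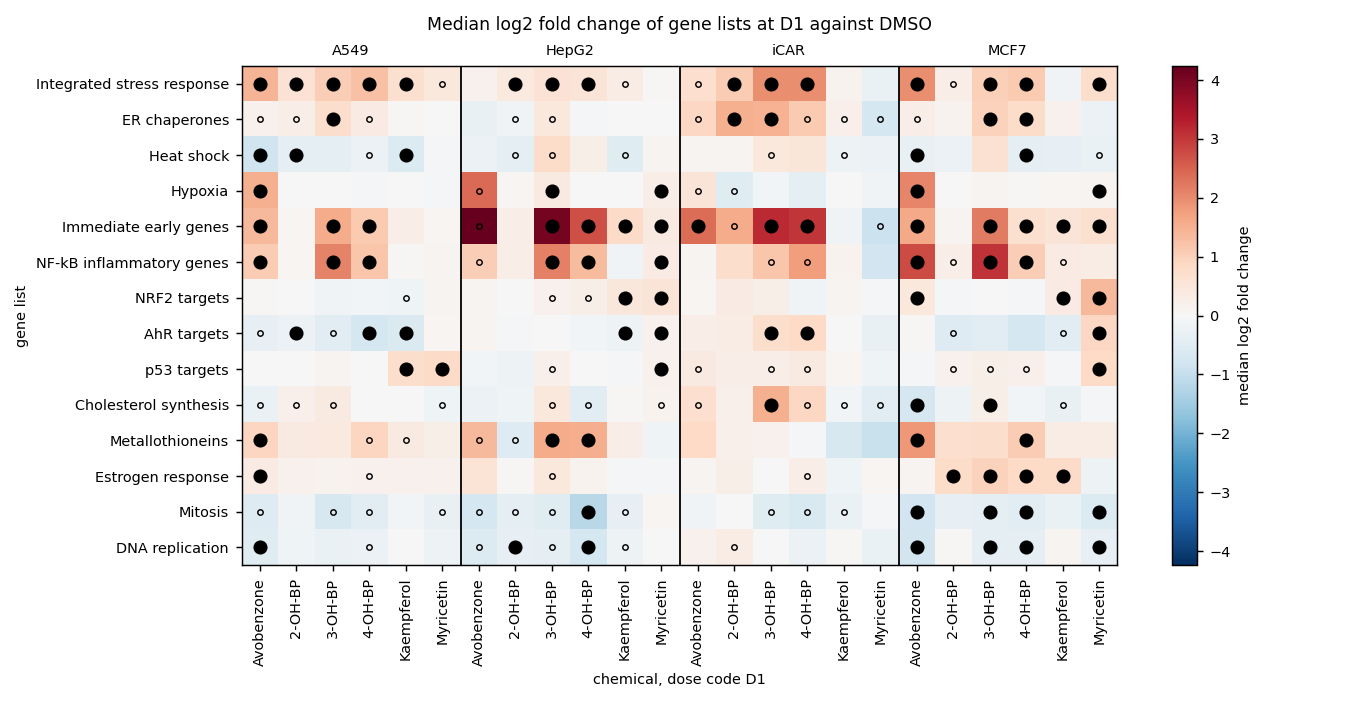
Median log2 fold change (colour) over the measured members of 14 gene lists (y axis) at D1 of each chemical (x axis) in 4 cell types, where circles mark lists called by camera at an adjusted p of 0.05 and filled circles those that held with an estimated correlation. With avobenzone the integrated stress response had a median of 1.43 in A549 and 1.96 in MCF7.

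**Figure D4:**
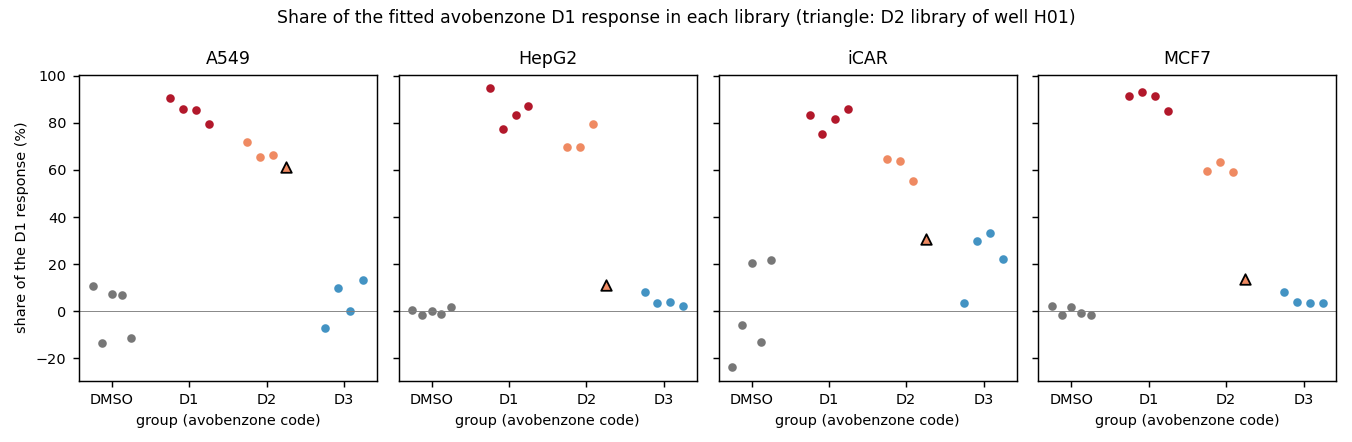
Share of the fitted avobenzone D1 response (y axis, percent) in each avobenzone and plate 10 vehicle library, by group (x axis) and cell type (panel), with the D2 library of well H01 as a triangle. That library lay below the other D2 libraries at 11% in HepG2, 30.8% in the cardiomyocytes (iCAR) and 13.5% in MCF7, and stood at 61.4% in A549.

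The cell types were then compared in their response to avobenzone. Of 11118 probes tested in all 4, 87 rose in all 4 at D1, against 1.1 if the calls were independent. Those that fell in all 4 were 26, against 0.849. GDF15, a secreted stress cytokine, rose by 1.64, 3.85, 3.0 and 2.64 in A549, HepG2, cardiomyocytes and MCF7. The angiogenic factor VEGFA rose by 2.2, 2.41, 1.83 and 2.71 in that order. Sterol genes went opposite ways. INSIG1 fell in A549 (-1.4 ± 0.22) and MCF7 (-1.73 ± 0.16) and rose in cardiomyocytes (2.6 ± 0.44). HMGCS1 fell in MCF7 (-1.25 ± 0.17) and rose in HepG2 (0.41 ± 0.14) and cardiomyocytes (1.68 ± 0.33). The LDL receptor, LDLR, fell in A549 (-1.26 ± 0.2) and MCF7 (-1.09 ± 0.14) and rose in HepG2 (2.43 ± 0.26). TIPARP, a target of the dioxin receptor, fell in A549 (-0.62 ± 0.15) and rose in HepG2 (1.38 ± 0.13) and MCF7 (0.94 ± 0.1).

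At D1 shared calls for rises in A549 and MCF7 exceeded the number for independent calls (447 against 81.2 expected; each cell type has vehicle libraries of its own). An excess of shared falls in cardiomyocytes and MCF7 was not found (103 against 92.9; Fisher's exact test over 12 pairs and directions and both codes, adjusted p = 0.144). The interaction test found 3684 of 11118 probes with effects that differed between cell types at D1, 1123 at D2 and 0 at D3 (edgeR). At D3 208 lay at an unadjusted p under 0.05, and DESeq2 called 0. The D2 count was 1833 without HepG2 avobenzone D2 replicate 4.

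3-Hydroxybenzophenone changed 1113 probes in A549, 4125 in HepG2, 2139 in cardiomyocytes and 1321 in MCF7 (edgeR, joint test of the 3 codes). At D1 alone it changed 1578, 4385, 2166 and 1900 in that order. In HepG2 at D1 the stress chaperone HSPA6 rose by 12.1 ± 0.59 for probe 21239 and at least 1630-fold for probe 3141, which had 0 vehicle counts. Heat shock genes rose there in 11 of 15 genes and 1 fell, with adjusted p = 0.172 with an estimated correlation. Of the immediate early list, 20 of 20 genes rose (FOSB (7.94 ± 0.5), EGR1 (6.18 ± 0.22)). NF-kB genes rose in 13 of 13 genes (CXCL2 (8.25 ± 0.34)) and metallothioneins in 8 of 8 genes. The triglyceride synthesis enzyme DGAT2 (-2.56 ± 0.14) and C10orf62 (-2.76 ± 0.71) fell. In A549 immediate early genes rose in 15 of 16 genes (EGR1 (7.92 ± 0.46)) and 1 fell. NF-kB genes rose in 14 of 16 genes (16 adjusted over the list alone) (CXCL8 (5.13 ± 0.25)) and ER chaperones in 9 of 16 genes (12 adjusted over the list alone) (HSPA5 (1.52 ± 0.15)). CCL20 was higher by 600-fold, 95% counting interval 166 to 4960, and FAM111B (-2.13 ± 0.28) and HSPA2 (-1.85 ± 0.19) fell.

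In cardiomyocytes 3-hydroxybenzophenone D1 raised cholesterol synthesis in 20 of 21 genes (INSIG1 (3.1 ± 0.38)). It raised the integrated stress response in 15 of 20 genes (18 adjusted over the list alone) and ER chaperones in 13 of 16 genes (15 adjusted over the list alone). Contractile genes fell in 10 of 21 genes (12 adjusted over the list alone). The orphan receptors NR4A2 (7.84 ± 0.84) and NR4A3 (7.41 ± 0.49) rose, and the sarcomere protein MYOZ1 (-2.6 ± 0.56) and IL31RA (-2.58 ± 0.55) fell. At D2 914 probes were called, with ER chaperones up in 14 of 16 genes (15 adjusted over the list alone) (PDIA4 (3.66 ± 0.6)). Contractile genes fell in 8 of 21 genes (12 adjusted over the list alone), among them the natriuretic peptide NPPB (-2.0 ± 0.25). In MCF7 estrogen response genes rose in 12 of 18 genes at D1 (ADORA1 (2.64 ± 0.31)). They rose in 10 of 18 genes (16 adjusted over the list alone) at D2 (the progesterone receptor, PGR (1.54 ± 0.24)) and in 8 of 18 genes (17 adjusted over the list alone) at D3. HSPA6 (7.23 ± 0.98) and CXCL8 (5.6 ± 0.76) rose in MCF7 at D1, and ACTR3C (-2.03 ± 0.41) and the deiodinase DIO2 (-1.97 ± 0.61) fell. Apart from heat shock in HepG2, each list call of 3-hydroxybenzophenone named here held with an estimated correlation (estrogen response at D3, adjusted p = 3.27e-07). Leaving out 1 library gave 655 to 712 without 3-hydroxybenzophenone D1 replicate 1 or 3 in A549. In cardiomyocytes it gave 3424 without 3-hydroxybenzophenone D3 replicate 4.

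4-Hydroxybenzophenone changed 391 probes in A549, 2828 in HepG2, 3055 in cardiomyocytes and 827 in MCF7 (edgeR, joint test). The D1 counts were 867, 4334, 2188 and 945. In HepG2 at D1 mitosis genes fell in 15 of 15 genes (PLK1 (-1.55 ± 0.32)). Immediate early genes rose in 18 of 20 genes (EGR1 (5.78 ± 0.25)) and metallothioneins in 7 of 8 genes. HSPA6 rose by 8.63 ± 0.8 (probe 21239), and the cell cycle inhibitor CDKN2C (-3.36 ± 0.5) and the tubulin TUBB4B (-2.67 ± 0.32) fell. In cardiomyocytes the integrated stress response rose in 14 of 20 genes (16 adjusted over the list alone) (DDIT3 (5.18 ± 0.36)) and immediate early genes in 17 of 19 genes (19 adjusted over the list alone). Contractile genes fell there in 10 of 21 genes (12 adjusted over the list alone) (CASQ2 (-0.94 ± 0.13)), as did SNCG (-3.6 ± 0.7) and MYOZ1 (-3.55 ± 0.43). The cholesterol exporter ABCA1 (2.17 ± 0.33) and NR4A3 (7.26 ± 0.53) rose, and EGR4 was at least 228-fold higher.

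In A549 4-hydroxybenzophenone D1 raised the integrated stress response in 9 of 20 genes (17 adjusted over the list alone). EGR1 (7.4 ± 0.85) rose, CCL20 was higher by 163-fold, 95% counting interval 44.8 to 1350, and CEP295NL (-3.62 ± 0.85) and the corepressor CTBP2 (-3.43 ± 0.9) fell. In MCF7 the integrated stress response rose in 13 of 20 genes (15 adjusted over the list alone) (DDIT3 (3.34 ± 0.28)), and the mitochondrial folate enzyme ALDH1L2 (3.75 ± 0.31) rose. Estrogen response genes rose in 8 of 18 genes (10 adjusted over the list alone) at D1, 10 of 18 genes (15 adjusted over the list alone) at D2 and 9 of 18 genes (12 adjusted over the list alone) at D3. SOX2 (-2.3 ± 0.34) and PRRT1B (-2.03 ± 0.19) fell at D1. The lists of 4-hydroxybenzophenone named here held with an estimated correlation (contractile genes, adjusted p = 0.036; estrogen response at D3, 5.36e-04). With 1 library left out the joint counts became 181 to 242 without 4-hydroxybenzophenone D1 replicate 1, 2, 3 or 4 and 614 without plate 10 vehicle replicate 5 in A549 and 1810 without 4-hydroxybenzophenone D1 replicate 2 in HepG2. They became 1496 without 4-hydroxybenzophenone D1 replicate 3 and 4595 without 4-hydroxybenzophenone D2 replicate 2 in cardiomyocytes and 491 to 541 without 4-hydroxybenzophenone D1 replicate 2, 3 or 4 and 2408 without 4-hydroxybenzophenone D3 replicate 2 in MCF7.

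2-Hydroxybenzophenone changed fewer probes, 2 in A549, 236 in HepG2, 38 in cardiomyocytes and 0 in MCF7 (edgeR, joint test). In MCF7 337 lay at an unadjusted p under 0.05, and DESeq2 called 46. At D1 the pseudokinase TRIB3, a target of the integrated stress response, rose in A549 (1.25 ± 0.17) and cardiomyocytes (3.28 ± 0.51). The list of that response rose in HepG2 in 10 of 19 genes (VLDLR (1.35 ± 0.13)). It rose in 6 of 20 genes (12 adjusted over the list alone) in cardiomyocytes and in 1 of 20 genes (8 adjusted over the list alone) in A549. CYP1A1, the dioxin-inducible monooxygenase, fell in HepG2 (-1.27 ± 0.1). In MCF7 at D1 the estrogen response list rose in 2 of 18 genes (8 adjusted over the list alone), and the called members were the adenosine receptor ADORA1 (2.95 ± 0.47) and the chemokine CXCL12 (1.36 ± 0.21). At D2 that list rose in 0 of 18 genes (5 adjusted over the list alone). Other named probes at D1 were TCIM (0.93 ± 0.14) in A549 and TEX54 (2.17 ± 0.53), LYRM4 (1.92 ± 0.45) and H2BC6 (-1.36 ± 0.31) in HepG2. In cardiomyocytes they were SP6 (2.87 ± 0.42), IL31RA (-3.01 ± 0.44) and RRAD (-1.93 ± 0.36). Each of these lists held with an estimated correlation (estrogen response, adjusted p = 2.49e-05 at D1 and 1.44e-06 at D2). The joint counts became 96 to 154 without plate 10 vehicle replicate 1, 2, 3, 4 or 5, 2-hydroxybenzophenone D1 replicate 2 or 4, 2-hydroxybenzophenone D2 replicate 2 or 2-hydroxybenzophenone D3 replicate 3 or 4 and 610 to 2425 without 2-hydroxybenzophenone D1 replicate 3 or 2-hydroxybenzophenone D3 replicate 1 in HepG2 and 19 to 23 without plate 10 vehicle replicate 2 or 4 or 2-hydroxybenzophenone D1 replicate 2 or 4 and 60 without 2-hydroxybenzophenone D2 replicate 3 in cardiomyocytes. The 0 of MCF7 became 1 to 21 without 2-hydroxybenzophenone D1 replicate 2 or 4, and the 2 of A549 became 0 to 1 without plate 10 vehicle replicate 1, 2 or 3, 2-hydroxybenzophenone D1 replicate 1, 3 or 4, 2-hydroxybenzophenone D2 replicate 1, 2, 3 or 4 or 2-hydroxybenzophenone D3 replicate 1, 2, 3 or 4 and 4 without plate 10 vehicle replicate 5.

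The isomers, which differ in the ring position of the hydroxyl group, were compared directly at matched codes, 4 against 4 libraries, as log2 differences. At D1 HSPA6 was lower with 2- than with 3-hydroxybenzophenone by -11.22 ± 0.77 in HepG2 and -6.38 ± 0.9 in MCF7. EGR1 differed between them by -7.02 ± 0.78 in A549, and the neurotrophic factor GDNF by -6.61 ± 0.96 in cardiomyocytes. Against 4-hydroxybenzophenone the differences were -6.51 ± 0.78 for EGR1 in A549 and -7.74 ± 0.76 for HSPA6 in HepG2. They were -6.19 ± 0.95 for GDNF in cardiomyocytes and -3.29 ± 0.31 for DDIT3 in MCF7. In the other direction the retinoid receptor RARB was higher with the 2-isomer in A549, by 2.59 ± 0.43 against the 3-isomer and 1.83 ± 0.32 against the 4-isomer. SOX2 was higher with the 2- than with the 4-isomer in MCF7 (2.13 ± 0.35). Between the 3- and the 4-isomer, interferon-induced IFIT2 (5.22 ± 0.74) and IFIT3 (3.96 ± 0.47) were higher with the 3-isomer in HepG2. FBXL13 (5.47 ± 0.96) and INSIG1 (2.08 ± 0.3) were higher with it in A549, and HSPA6 (5.6 ± 0.84) and interferon lambda 2, IFNL2 (4.66 ± 0.76), in MCF7. ABCA1 was lower with it in cardiomyocytes (-1.92 ± 0.33), and RRM2, a ribonucleotide reductase subunit, in HepG2 (-3.87 ± 1.05). With the counts of all RRM2 probes summed, that difference was 0.64 (adjusted p = 0.0997, edgeR).

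By the joint test over the 3 codes, 2- and 3-hydroxybenzophenone differed at 818, 2753, 204 and 396 probes in A549, HepG2, cardiomyocytes and MCF7 (edgeR). In the same order, 2- and 4-hydroxybenzophenone differed at 158, 1830, 418 and 219 probes. The 3- and 4-isomers differed at 223, 690, 1 and 59. Where the 3- and 4-isomers did not differ past the threshold at D1, the intervals of the difference were narrow for some genes and wide for others. Their widths are only approximate for differences near 0. In cardiomyocytes DDIT3 differed by -0.36, 95% interval -1.07 to 0.36, HSPA5 by 0.46, 95% interval -0.18 to 1.1, INSIG1 by 0.93, 95% interval -0.19 to 2.05 and NPPB by -0.3, 95% interval -1.23 to 0.63. In MCF7 GDF15 differed by -0.01, 95% interval -0.26 to 0.25 and DDIT3 by 0.38, 95% interval -0.19 to 0.96. The fixed estrogen-responsive genes of MCF7 did not differ past the threshold between any isomers at D2 or D3. PGR at D2 differed by 0.01, 95% interval -0.63 to 0.65 between the 3- and 4-isomers and by -0.41, 95% interval -1.05 to 0.23 between the 2- and 3-isomers. TFF1 at D2 differed by -0.25, 95% interval -0.7 to 0.21 between the 2- and 3-isomers. At D3 PGR was -1.17, 95% interval -1.83 to -0.51 between them, a difference that did not pass the adjustment (adjusted p = 0.559, edgeR).

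Single libraries moved these counts. The 2- and 3-isomers differed at 500 to 532 without 3-hydroxybenzophenone D1 replicate 1 or 2-hydroxybenzophenone D1 replicate 4 in A549, at 88 to 108 without 3-hydroxybenzophenone D1 replicate 3 or 2-hydroxybenzophenone D1 replicate 1, 2 or 4 and 498 without 2-hydroxybenzophenone D1 replicate 3 in cardiomyocytes and at 242 without 3-hydroxybenzophenone D1 replicate 3 in MCF7. The 2- and 4-isomers differed at 101 without 4-hydroxybenzophenone D1 replicate 4 in A549, at 194 to 216 without 2-hydroxybenzophenone D1 replicate 1 or 2 or 4-hydroxybenzophenone D1 replicate 3 in cardiomyocytes and at 112 to 127 without 4-hydroxybenzophenone D1 replicate 2, 3 or 4 in MCF7. The 3- and 4-isomers differed at 53 to 129 without 3-hydroxybenzophenone D1 replicate 1, 2 or 3 or 4-hydroxybenzophenone D1 replicate 1 or 2 in A549 and at 191 to 289 without 3-hydroxybenzophenone D1 replicate 2 or 3 or 4-hydroxybenzophenone D1 replicate 2 or 3 and 1099 to 1142 without 4-hydroxybenzophenone D1 replicate 1 or 4-hydroxybenzophenone D2 replicate 3 in HepG2. In cardiomyocytes they differed at 0 without 3-hydroxybenzophenone D2 replicate 1, 2, 3 or 4 or 4-hydroxybenzophenone D2 replicate 1, 2 or 4 and 2 to 33 without 3-hydroxybenzophenone D1 replicate 3 or 4 or 4-hydroxybenzophenone D2 replicate 3, and in MCF7 at 18 to 31 without 3-hydroxybenzophenone D1 replicate 3 or 4-hydroxybenzophenone D1 replicate 1, 3 or 4.

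Kaempferol lowered CYP1A1 at D1 in HepG2 (-2.4 ± 0.14), MCF7 (-3.18 ± 0.36) and A549 (-2.53 ± 0.46). In A549 the AhR list fell in 4 of 9 genes (5 adjusted over the list alone). In MCF7 estrogen response genes rose in 11 of 18 genes (14 adjusted over the list alone) at D1 (ADORA1 (2.56 ± 0.24)) and in 8 of 18 genes (14 adjusted over the list alone) at D2. In A549 p53 targets rose in 8 of 18 genes (13 adjusted over the list alone) and heat shock genes fell in 5 of 15 genes (8 adjusted over the list alone). There WDR78 (3.88 ± 0.55) rose, and VAV3 (-2.23 ± 0.3) and the NF-kB cofactor BCL3 (-2.21 ± 0.21) fell. In HepG2 NRF2 targets rose in 11 of 19 genes (the glutathione synthesis subunit GCLM (1.13 ± 0.06)) and 1 fell. Immediate early genes rose in 10 of 20 genes (11 adjusted over the list alone), and DNHD1 (3.66 ± 0.39) and TBXAS1 (3.44 ± 0.35) rose. Heat shock genes fell in 11 of 15 genes (12 adjusted over the list alone) and interferon genes in 4 of 10 genes (7 adjusted over the list alone) (IFIT1 (-2.74 ± 0.32)). These had adjusted p = 0.0626 and 0.0602 with an estimated correlation, and the other lists of kaempferol named here held with it. In cardiomyocytes the insulin receptor substrate IRS2 (1.52 ± 0.28) and CCN2 (1.22 ± 0.22) rose, and IL31RA (-2.21 ± 0.38) and ATP6V1FNB (-1.83 ± 0.31) fell. The joint test called 316, 1651, 30 and 438 probes in A549, HepG2, cardiomyocytes and MCF7 (edgeR). Leaving out 1 library gave 148 to 188 without kaempferol D1 replicate 1, 2, 3 or 4 and 518 without plate 10 vehicle replicate 5 in A549 and 915 to 1047 without kaempferol D1 replicate 1 or 3 and 2572 without kaempferol D1 replicate 4 in HepG2. It gave 10 to 19 without plate 10 vehicle replicate 2 or 4, kaempferol D1 replicate 2, 3 or 4, kaempferol D2 replicate 2 or kaempferol D3 replicate 1, 2 or 3 and 1187 without kaempferol D1 replicate 1 in cardiomyocytes and 239 to 284 without plate 10 vehicle replicate 1, 2, 3 or 4 or kaempferol D3 replicate 1, 2 or 4 and 1273 without kaempferol D2 replicate 1 in MCF7.

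The joint test of myricetin called 797 probes in MCF7, 22 in A549, 12 in HepG2 and 0 in cardiomyocytes (edgeR), and whether its effect differs between cell types was not tested. In cardiomyocytes 2120 lay at an unadjusted p under 0.05, and DESeq2 called 396. At D1 in MCF7 AhR targets rose in 8 of 9 genes, with CYP1A1 (2.15 ± 0.12), which also rose at D2 (0.85 ± 0.12). NRF2 targets rose in 15 of 20 genes (18 adjusted over the list alone), with heme oxygenase 1, HMOX1 (3.72 ± 0.23), and SLC7A11 (3.29 ± 0.21). Targets of p53 rose in 13 of 20 genes (19 adjusted over the list alone), with GDF15 (2.94 ± 0.09) and the death receptor FAS (2.56 ± 0.17). The integrated stress response rose in 11 of 20 genes (14 adjusted over the list alone), and mitosis genes fell in 13 of 15 genes (14 adjusted over the list alone). EID3 (3.52 ± 0.44) rose and AKAP5 (-1.26 ± 0.26) and SAMD11 (-1.25 ± 0.19) fell. In A549 p53 targets rose in 6 of 18 genes (12 adjusted over the list alone), with the p53 ligase MDM2 (1.4 ± 0.15) and GDF15 (1.77 ± 0.24). There PPAN (-1.05 ± 0.21) and the inhibitor of differentiation ID1 (-1.04 ± 0.15) fell. In HepG2 NRF2 targets rose in 5 of 19 genes (13 adjusted over the list alone) (GCLM (1.22 ± 0.09)). NCF2 (1.76 ± 0.28) and IGFBP1 (1.67 ± 0.26) rose, and PAQR8 (-1.0 ± 0.15) and ID1 (-0.97 ± 0.12) fell. All of these lists held with an estimated correlation. With single libraries left out the joint counts were 8 to 11 without myricetin D1 replicate 1, 2 or 3 in A549 and 7 without myricetin D1 replicate 1 in HepG2. In MCF7 the count was 437 to 492 without myricetin D1 replicate 1, 2 or 3 and 2703 without myricetin D3 replicate 1.

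Kaempferol and myricetin, which differ in the hydroxyl groups of a ring, were compared as differences from the vehicle of their own plates. At D1 CYP1A1 was lower with kaempferol than with myricetin in MCF7 (-5.34 ± 0.36), HepG2 (-3.19 ± 0.24) and A549 (-2.55 ± 0.62). CYP1B1 was lower in A549 (-2.44 ± 0.4) and MCF7 (-1.94 ± 0.3). In MCF7 HMOX1 (-3.24 ± 0.39), the p53 target MDM2 (-1.63 ± 0.11) and GDF15 (-2.1 ± 0.15) were lower with kaempferol. ADORA1 (3.48 ± 0.37) and PGR (1.25 ± 0.32) were higher. In HepG2 DNHD1 (4.16 ± 0.71) and GDF15 (1.58 ± 0.15) were higher with kaempferol, and in A549 GDF15 was lower (-1.56 ± 0.29). In cardiomyocytes SIK1 (2.79 ± 0.54) was higher and IL31RA (-3.29 ± 0.53) lower. None of the 35 fixed genes measured differed past the threshold there at D1. The difference of DDIT3 was 0.87, 95% interval -0.24 to 1.98 and that of HMOX1 0.12, 95% interval -3.18 to 3.43. The joint test called 159, 275, 9 and 525 probes in A549, HepG2, cardiomyocytes and MCF7 (edgeR). These counts became 81 to 105 without kaempferol D1 replicate 1, 2 or 3, kaempferol D3 replicate 2 or myricetin D1 replicate 2, 3 or 4 in A549 and 148 to 181 without kaempferol D1 replicate 3 or myricetin D1 replicate 1 or 2 and 487 without plate 11 vehicle replicate 5 in HepG2. They became 5 without kaempferol D1 replicate 2 and 20 without plate 11 vehicle replicate 5 in cardiomyocytes and 322 to 343 without myricetin D1 replicate 2 or 3 and 818 to 1318 without kaempferol D1 replicate 1 or 2 or kaempferol D2 replicate 1 in MCF7.

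Vehicle libraries of the plates were compared within each cell type, 5 against 5, to measure what a plate alone changed. In MCF7 HMGN2 (1.47 ± 0.25) and ZNF326 (1.27 ± 0.26) were higher on plate 11. The mitochondrial ribosomal gene MRPL47 (-1.81 ± 0.29) and SIVA1 (-1.47 ± 0.21) were lower. In HepG2 ZNF485 (1.58 ± 0.33) and cytochrome c, CYCS (1.45 ± 0.31), were higher and OSBPL2 (-1.55 ± 0.38) and POLR1D (-1.51 ± 0.29) lower. In A549 the liver apolipoprotein APOB was at least 103-fold higher on plate 11, from 0 counts to 17.4 CPM. Over the 17 plate 11 libraries of A549, ALB, APOA1, SERPINA1, TF, AHSG and APOB exceeded plate 10 by 0.099 to 0.119% of their HepG2 level. The counts were 3397 probes in MCF7, 2500 in HepG2, 2 in A549 and 0 in cardiomyocytes (edgeR). In cardiomyocytes 3150 lay at an unadjusted p under 0.05, and DESeq2 called 739. The HepG2 count rested on single libraries, with 0 without plate 10 vehicle replicate 1, 2, 3, 4 or 5 or plate 11 vehicle replicate 1, 2, 3 or 4 and 6767 without plate 11 vehicle replicate 5. That of MCF7 was 2124 without plate 10 vehicle replicate 4. With the 2 leading axes of spread within treated groups as covariates the counts were 1 in HepG2, 560 in MCF7 and 129 in A549. Plate and chemical coincide for myricetin, so its values and those of the other chemicals also differ by plate, and the flavonol comparison removes a plate difference only as far as it is additive on the log scale.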

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

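Tests of the avobenzone library in well H01, the fit without it and the comparison of totals by well were chosen after results were seen. So were fits with the well as block or scores of spread as covariates. Tests of HepG2 signal in A549 and plate depth followed patterns in the data.

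Of the 40 fixed genes, 6 were called with avobenzone in opposite directions in different cell types. The differences between effects (edgeR interaction, log2 difference ± SE, D1 before D2) measure them but are no further evidence, since the genes were picked for opposite calls, and no gene list was tested between cell types. LDLR, the receptor that takes up low-density lipoprotein, rose in HepG2 and fell in A549 (HepG2 minus A549 3.63 ± 0.34 and 3.22 ± 0.34) and in MCF7 (MCF7 minus HepG2 -3.47 ± 0.33 and -2.99 ± 0.33). At D2 it also rose in the cardiomyocytes (cardiomyocytes minus A549 2.44 ± 0.34, MCF7 minus cardiomyocytes -2.21 ± 0.32). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose in the cardiomyocytes and fell in A549 (cardiomyocytes minus A549 3.98 ± 0.54 and 4.42 ± 0.55) and in MCF7 (MCF7 minus cardiomyocytes -4.32 ± 0.52 and -4.23 ± 0.52). The sterol synthesis gene HMGCS1 rose in the cardiomyocytes and fell in MCF7 (-2.92 ± 0.34 and -3.06 ± 0.34), and at D1 it rose in HepG2 (MCF7 minus HepG2 -1.62 ± 0.33). At D1, CPT1A, the carnitine shuttle enzyme of fatty acid oxidation, rose in the cardiomyocytes and fell in MCF7 (-1.52 ± 0.27). TIPARP, a target of the aryl hydrocarbon receptor, fell in A549 and rose in HepG2 (HepG2 minus A549 1.95 ± 0.21 and 1.62 ± 0.21) and in MCF7 (MCF7 minus A549 1.56 ± 0.21 and 1.38 ± 0.21). The haem oxygenase gene HMOX1 fell in A549 and rose in MCF7 at D2 (1.35 ± 0.33, adjusted p = 0.0429, the highest of these). Over all probes, effects differed between cell types at 3684 at D1 and 1123 at D2 (2370 without well H01).

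In the HepG2, cardiomyocyte and MCF7 plates, the avobenzone D2 library of well H01 (replicate 4) had response shares of 11%, 30.8% and 13.5%. The other D2 libraries had 73 ± 5.51%, 61.3 ± 5.15% and 60.6 ± 2.27% (SD, n = 3). A shallower library was argued against, since the other libraries thinned to its total stayed at 55.4% or more (an earlier comparison of totals alone could not decide), and a swap with a D3 or vehicle library was argued against in HepG2 and MCF7, where none exceeded 8.27%. The A549 library of that well stood at 61.4% beside 68 ± 3.4% (SD, n = 3). It argued against compound missing from a source well shared by the 4 cell types, and against a position that mutes all 4. With 1 called probe, the myricetin D2 group in MCF7 (H01 15.2%, among 10.5 to 17.5%) had little to mute. In the cardiomyocytes a swap cannot be told apart, because a D3 library reached 33.2% and vehicle libraries ran from -23.5 to 21.6%. Lower exposure in those wells stays open and untested, and no biological explanation was tested.

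Plate 11 libraries of A549 held transcripts of hepatocytes: the apolipoprotein gene APOB stood at 16.9 ± 2.78 CPM (SD, n = 17) against 0.123 CPM on plate 10 (n = 65), and the albumin gene ALB at 4.47 ± 1.25 against 0.0413 CPM. Of 15 hepatocyte markers, 6 were abundant in HepG2 and nearly absent from A549 on plate 10 (A549 itself expressed the fibrinogen genes). Their rises over plate 10, 0.099 to 0.119% of the HepG2 level, differed by a ratio of 1.2, as a fixed share of HepG2 RNA or reads could give. The HepG2 library of the same well as the source was argued against, since over 17 wells the HepG2 signal had Spearman's rho = -0.0588 with the ratio of totals (permutation p = 0.825, upper 95% bound 0.434; Pearson's r = 0.289, permutation p = 0.251, and -0.197 without the 2 farthest wells). APOB also stood at 7.44 CPM in cardiomyocyte libraries of plate 11 and 1.24 CPM on plate 10. Where the signal entered stays open, and no biological explanation was tested.

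Vehicle libraries of plates 10 and 11 differed at 2500 probes in HepG2 and 3397 in MCF7. A difference in depth was argued against, since 81% and 92.2% of these probes were still called after thinning to the lowest total. With scores on the 2 leading axes of spread within treated groups as covariates, 0% stayed called in HepG2 and 7.92% in MCF7. Their median absolute log2 difference went from 0.664 to 0.116 and from 0.482 to 0.289. The axes may thus separate the plates. Plate explained 49.1% and 37.3% of the vehicle scores in HepG2 and 26.2% and 62.9% in MCF7. Part of the loss thus comes from overlap of axes and plate. What the axes stand for stays open, and no biological explanation was tested, as the plates share cell type and vehicle.

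By Dixon's test, single libraries stood apart from their group in total count or response share. Chance flags about 1 in 20 groups, or 4 of the 80 groups tested for total counts, where 7 were found, and 2.55 of the 51 tested for response shares, where 6 were found, with both H01 libraries of HepG2 and MCF7 among them. These tallies count a well that recurs in several cell types as separate groups. Totals of the same well, less their group mean, had Spearman's rho of 0.67 to 0.695 among HepG2, the cardiomyocytes and MCF7 and -0.308 to -0.241 between these and A549 (n = 82, permutation test, adjusted p at most 0.0481), so totals recurred by well; the cause was not tested. Total counts were high in HepG2 for avobenzone D1 replicate 2 (6240778, others 4778209 to 4970607), 4-hydroxybenzophenone D1 replicate 3 (7996915, others 4974531 to 5194388) and myricetin D2 replicate 2 (6393821, others 4717899 to 4821562). The cardiomyocyte library of avobenzone D1 replicate 2 held 6170479 counts (others 4399275 to 4687205). In MCF7, 3-hydroxybenzophenone D2 replicate 3 held 6123166 (others 4532332 to 4607804), 4-hydroxybenzophenone D1 replicate 3 held 8100142 (others 4848510 to 5399665) and kaempferol D2 replicate 2 held 5815995 (others 4581448 to 4787823). Response shares in MCF7 stood apart for avobenzone D3 replicate 1 (8.27%, others 3.45 to 3.73%), 4-hydroxybenzophenone D3 replicate 2 (19.6%, others 27.1 to 28.5%) and kaempferol D3 replicate 3 (14.1%, others -5.24 to -4.31%). Along the 3-hydroxybenzophenone response, vehicle replicate 5 of A549 plate 10 stood at -7.99% (others 0.702 to 3.32%).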

How the results depend on the processing

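The fits without libraries that stood apart, without well H01, with axes of spread as covariates and with the well as a block were chosen after seeing the data, and the other alternatives were planned. Of the 55 counts of probes past the threshold, all stayed within 1.5 times with DESeq2's size factors in place of TMM, 54 with counts summed per gene and 52 without libraries that stood apart, which left 28 of the 37 fits as they were. The other limits on library totals say little, since 35 fits kept the same libraries at 500000 counts and all 37 without a minimum. Without a count filter 46 stayed, with DESeq2 21, in whole-plate fits 16 of 28 and in fits of the compared groups alone 8 of 12. Between TMM and DESeq2's size factors, the only other scaling tried, the mean scaling of the groups compared shifted by at most 0.0252 in log2 (76 comparisons). Named genes lost their call 9 times with DESeq2's size factors, 60 times without the filter, 4 times with DESeq2 (5 had no adjusted p), 9 times per gene, 122 of 1172 times in whole-plate fits, 47 of 462 in fits of the compared groups and 6 of 144 without libraries that stood apart. Leaving out single libraries ended 319 of 1483 calls and turned the direction of 0. With counts summed per gene, 2 differences between chemicals turned: HSPD1 for kaempferol minus myricetin (A549, D1) went from 1.96 to -0.276 (adjusted p = 0.237, edgeR) and RRM2 for 3- minus 4-hydroxybenzophenone (HepG2, D1) from -3.87 to 0.637 (adjusted p = 0.0997, edgeR). Of 426 list calls by camera, 190 held with an estimated correlation and 319 by fry, and 0 turned. No paired analysis was possible between treatments because these share no well on a plate, but wells recur across cell types and, for vehicle, on both plates. With the well as a block, avobenzone effects differed between cell types at 3811 probes at D1, 1131 at D2 and 0 at D3 (203 at an unadjusted p under 0.05; edgeR). Vehicle plates went from 2 to 0 in A549 (118), 2500 to 0 in HepG2 (4620) and 3397 to 4069 in MCF7, with 4 residual degrees of freedom, and 5 of 9 named genes lost their call. Deviations from the group mean correlated over 0.1 between libraries of 1 well in 40 of 102 pairs across cell types and 5 of 20 across plates, and in 36 and 6 a library correlated best with its own well (24 by chance across cell types, permutation p = 0.0074). Libraries of 1 well thus share part of their spread, although not every pair passed 0.1. The main fits did not pair wells. The main test between cell types and the numbers expected for independent calls therefore leave this shared spread out.

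For the counts that moved further, the cause was not tested, except that leaving out libraries lowers the number compared. edgeR called 0 probes for avobenzone D3 in A549, the cardiomyocytes and MCF7 (unadjusted p under 0.05 at 260, 1376 and 115 probes; DESeq2 0, 2 and 1). It called 0 for 2-hydroxybenzophenone in MCF7 (337; DESeq2 46), myricetin in the cardiomyocytes (2120; DESeq2 396) and the cardiomyocyte vehicle plates (3150; DESeq2 739). 2-hydroxybenzophenone with DESeq2 went from 2 to 30 in A549, 236 to 1034 in HepG2, 38 to 151 in the cardiomyocytes and 0 to 46 in MCF7. 4-hydroxybenzophenone with DESeq2 went from 391 to 907 in A549, 3055 to 4739 in the cardiomyocytes and 827 to 1607 in MCF7. Kaempferol with DESeq2 went from 316 to 640 in A549, 30 to 1020 in the cardiomyocytes and 438 to 1602 in MCF7. Myricetin with DESeq2 went from 22 to 136 in A549, 12 to 84 in HepG2, 0 to 396 in the cardiomyocytes and 797 to 1379 in MCF7. Avobenzone with DESeq2 went from 850 to 1280 at D2 in the cardiomyocytes, 0 to 2 at D3 in the cardiomyocytes and 0 to 1 at D3 in MCF7. 3-hydroxybenzophenone with DESeq2 went from 2139 to 3292 in the cardiomyocytes. 2- minus 4-hydroxybenzophenone with DESeq2 went from 158 to 284 in A549, 418 to 658 in the cardiomyocytes and 219 to 479 in MCF7. 3- minus 4-hydroxybenzophenone with DESeq2 went from 223 to 470 in A549, 690 to 1239 in HepG2, 1 to 9 in the cardiomyocytes and 59 to 109 in MCF7. Kaempferol minus myricetin with DESeq2 went from 159 to 319 in A549, 275 to 530 in HepG2, 9 to 86 in the cardiomyocytes and 525 to 1153 in MCF7. Vehicle plates with DESeq2 went from 2 to 10 in A549, 2500 to 4041 in HepG2 and 0 to 739 in the cardiomyocytes. 2- minus 3-hydroxybenzophenone with DESeq2 went from 204 to 353 in the cardiomyocytes and 396 to 666 in MCF7. Without a count filter, vehicle plates in A549 went from 100 to 83.3% higher calls. Avobenzone without the filter went from 0 to 3 at D3 in A549. 4-hydroxybenzophenone without the filter went from 391 to 670 in A549. 3- minus 4-hydroxybenzophenone without the filter went from 223 to 135 in A549 and 1 to 2 in the cardiomyocytes. Kaempferol minus myricetin without the filter went from 159 to 77 in A549, 275 to 158 in HepG2 and 9 to 5 in the cardiomyocytes. Vehicle plates without the filter went from 2 to 6 in A549. 2- minus 4-hydroxybenzophenone without the filter went from 219 to 144 in MCF7. Avobenzone in whole-plate fits went from 1473 to 2313 at D1 in A549, 910 to 1606 at D2 in A549 and 0 to 1 at D3 in the cardiomyocytes. 2-hydroxybenzophenone in whole-plate fits went from 2 to 34 in A549, 236 to 57 in HepG2, 38 to 285 in the cardiomyocytes and 0 to 61 in MCF7. 3-hydroxybenzophenone in whole-plate fits went from 1113 to 1801 in A549. 4-hydroxybenzophenone in whole-plate fits went from 391 to 951 in A549. Kaempferol in whole-plate fits went from 316 to 483 in A549, 1651 to 941 in HepG2 and 30 to 58 in the cardiomyocytes. Avobenzone in fits of the 2 compared groups went from 910 to 495 at D2 in A549, 2023 to 1325 at D1 in the cardiomyocytes, 850 to 244 at D2 in the cardiomyocytes and 0 to 1 at D3 in MCF7. 2-hydroxybenzophenone with counts summed per gene went from 0 to 1 in MCF7. 2-hydroxybenzophenone without libraries that stood apart went from 0 to 21 in MCF7. Kaempferol minus myricetin without libraries that stood apart went from 9 to 20 in the cardiomyocytes. 3- minus 4-hydroxybenzophenone without libraries that stood apart went from 59 to 106 in MCF7. Vehicle plates with the axes as covariates went from 2 to 129 in A549, 2500 to 1 in HepG2 and 3397 to 560 in MCF7. Avobenzone between cell types without well H01 went from 1123 to 2370 at D2.

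With single libraries left out, 40 of the 55 counts moved by over 1.5 times. Avobenzone ran from 917 to 1800 at D1 in A549, 474 to 1064 at D2 in A549, 1606 to 4552 at D2 in HepG2, 1257 to 2486 at D1 in the cardiomyocytes, 338 to 1970 at D2 in the cardiomyocytes and 303 to 1294 at D2 in MCF7. 2-hydroxybenzophenone ran from 0 to 4 in A549, 96 to 2425 in HepG2, 19 to 60 in the cardiomyocytes and 0 to 21 in MCF7. 3-hydroxybenzophenone ran from 655 to 1398 in A549 and 1443 to 3424 in the cardiomyocytes. 4-hydroxybenzophenone ran from 181 to 614 in A549, 1810 to 3247 in HepG2, 1496 to 4595 in the cardiomyocytes and 491 to 2408 in MCF7. Kaempferol ran from 148 to 518 in A549, 915 to 2572 in HepG2, 10 to 1187 in the cardiomyocytes and 239 to 1273 in MCF7. Myricetin ran from 8 to 27 in A549, 7 to 15 in HepG2 and 437 to 2703 in MCF7. 2- minus 3-hydroxybenzophenone ran from 500 to 902 in A549, 88 to 498 in the cardiomyocytes and 242 to 507 in MCF7. 2- minus 4-hydroxybenzophenone ran from 101 to 174 in A549, 194 to 595 in the cardiomyocytes and 112 to 311 in MCF7. 3- minus 4-hydroxybenzophenone ran from 53 to 315 in A549, 191 to 1142 in HepG2, 0 to 33 in the cardiomyocytes and 18 to 81 in MCF7. Kaempferol minus myricetin ran from 81 to 191 in A549, 148 to 487 in HepG2, 5 to 20 in the cardiomyocytes and 322 to 1318 in MCF7. Vehicle plates ran from 0 to 6767 in HepG2 and 2124 to 4503 in MCF7. Avobenzone between cell types ran from 809 to 1833 at D2.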

Other observations

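The gene groups described here were picked from the fixed lists after their values were seen, and the tests of other splits had been set beforehand.

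Genes of the glucocorticoid response list rose with avobenzone and with 3- and 4-hydroxybenzophenone. In A549, avobenzone D1 raised 2 of 7 genes, namely ERRFI1 (3.19 ± 0.17), a feedback inhibitor of EGF receptor signalling, and TSC22D3 (3.15 ± 0.21), a leucine zipper repressor. In MCF7 it raised 5 of 7 genes, among them ERRFI1 (3.99 ± 0.35) and the clock gene PER1 (1.55 ± 0.13). FKBP5, the direct receptor target that encodes a co-chaperone of the receptor, stood at -0.04 ± 0.19 in A549 and -0.25 ± 0.12 in MCF7, neither past the threshold. With 3-hydroxybenzophenone D1 in the cardiomyocytes, 6 of 8 genes (7 adjusted over the list alone) rose, FKBP5 (1.23 ± 0.2) among them, with the kinase gene SGK1 (3.19 ± 0.52) and the zinc finger gene ZBTB16 (2.94 ± 0.66). With 4-hydroxybenzophenone D1 in these cells 5 of 8 genes (7 adjusted over the list alone) rose, including FKBP5 (0.79 ± 0.23) and ZBTB16 (3.9 ± 0.73). In HepG2, 3-hydroxybenzophenone D1 raised 4 of 6 genes, and in MCF7 it raised 4 of 7 and lowered 1, CRISPLD2 (-0.7 ± 0.21). FKBP5 stood at -0.08 ± 0.09 and -0.15 ± 0.14 there, again short of the threshold. Each of these list calls also passed camera with an estimated correlation, with adjusted p from 2.09e-04 (avobenzone, A549) to 0.0468 (4-hydroxybenzophenone, cardiomyocytes). Whether the lists' changes differ between cell types was not tested.

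Autophagy and lysosome genes rose in HepG2 with 3-hydroxybenzophenone D1 in 8 of 13 genes, led by RRAGD (1.84 ± 0.37), a GTPase that signals nutrients to mTORC1, and the autophagy receptor SQSTM1 (1.6 ± 0.17). With 4-hydroxybenzophenone D1, 10 of 13 genes rose (and 1 fell adjusted over the list alone), among them SQSTM1 (1.54 ± 0.23) and the mTORC1 regulator FLCN (1.43 ± 0.23). Avobenzone D1 raised 5 of 12 genes in MCF7, led by MAP1LC3B (1.85 ± 0.16), which coats autophagosomes. Of the apoptosis regulators, 3-hydroxybenzophenone D1 raised 3 of 11 genes in MCF7, the pro-death genes PMAIP1 (3.46 ± 0.87), HRK (2.56 ± 0.59) and BCL2L11 (1.4 ± 0.07). In HepG2, 4-hydroxybenzophenone D1 raised 3 of 8 genes (4 adjusted over the list alone) of that list, led by the survival genes MCL1 (3.04 ± 0.12) and BCL2L1 (1.4 ± 0.31). These list calls passed with an estimated correlation too.

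The labels of the same libraries were exchanged at random, within each cell type for the test between cell types, within each dose code for the isomers and within each plate for the flavonols. With the real one included, 100 groupings were counted per result against vehicle or between vehicle plates and 50 per other result. These replaced smaller draws. Pairs are the probes called with the real labels and the highest count of the other groupings. Excluded means only that under 4% called as many, unadjusted for the number of results. For avobenzone, chance can be excluded at D1 in A549 (1473, 999), at D2 in A549 (910, 2571), at D1 in HepG2 (4992, 2493), at D2 in HepG2 (2892, 1957), at D1 in the cardiomyocytes (2023, 3072), at D1 in MCF7 (3116, 1611) and at D2 in MCF7 (604, 527). For 3-hydroxybenzophenone, it can be excluded in A549 (1113, 1846), in HepG2 (4125, 662), in the cardiomyocytes (2139, 2761) and in MCF7 (1321, 1106). For 4-hydroxybenzophenone, it can be excluded in A549 (391, 251), in HepG2 (2828, 968) and in the cardiomyocytes (3055, 2228). For myricetin, it can be excluded in MCF7 (797, 1538). For kaempferol, it can be excluded in HepG2 (1651, 540), in the cardiomyocytes (30, 3563) and in MCF7 (438, 1). For 2- minus 3-hydroxybenzophenone, it can be excluded in A549 (818, 2), in HepG2 (2753, 25) and in MCF7 (396, 358). For 2- minus 4-hydroxybenzophenone, it can be excluded in the cardiomyocytes (418, 409) and in MCF7 (219, 132). For kaempferol minus myricetin, it can be excluded in A549 (159, 3), in HepG2 (275, 0) and in MCF7 (525, 0). For the vehicle plates, it can be excluded in MCF7 (3397, 245). For avobenzone between cell types, it can be excluded at D1 (3684, 2752). For the vehicle plates in HepG2 (2500, 5541) 3 of 100 groupings called as many. The count fell to 0 in other fits, so chance is left open there.

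For avobenzone, chance cannot be excluded at D2 in the cardiomyocytes (850, 3667). For 2- minus 4-hydroxybenzophenone, it cannot be excluded in A549 (158, 337). For 3- minus 4-hydroxybenzophenone, it cannot be excluded in HepG2 (690, 4961) and in the cardiomyocytes (1, 1). For 2- minus 3-hydroxybenzophenone, it cannot be excluded in the cardiomyocytes (204, 925). Where 4 to 6% of the groupings called as many probes, another draw could place the results across the line of 5%. Whether chance can be excluded there is uncertain. These were, just under the line, kaempferol in A549 (316, 2281), 4-hydroxybenzophenone in MCF7 (827, 2854), 3- minus 4-hydroxybenzophenone in A549 (223, 308) and in MCF7 (59, 59) and avobenzone between cell types at D2 (1123, 1127) and, at or just over it, 2-hydroxybenzophenone in A549 (2, 2832) and in HepG2 (236, 3313), 2- minus 4-hydroxybenzophenone in HepG2 (1830, 3885), kaempferol minus myricetin in the cardiomyocytes (9, 3029) and the vehicle plates in A549 (2, 4413). Other groupings called at least 2 times as many probes as the real one for avobenzone at D2 in A549 and at D2 in the cardiomyocytes, 2- minus 4-hydroxybenzophenone in A549 and in HepG2, 3- minus 4-hydroxybenzophenone in HepG2, 2- minus 3-hydroxybenzophenone in the cardiomyocytes and the vehicle plates in A549 and in HepG2, where only the 2 groups compared exchanged libraries, which points to a structure of the samples beside the labels. In the joint tests against vehicle and the flavonol difference libraries were exchanged across codes, so effects of the codes could give such counts, which was not tested. Where edgeR called 0 probes with the real labels, any grouping gives as many, so these groupings decide nothing. These were, each with the highest other count, the probes at an unadjusted p under 0.05 and the DESeq2 count, avobenzone at D3 in A549 (4200, 260, 0), at D3 in HepG2 (0, 90, 0), at D3 in the cardiomyocytes (5929, 1376, 2) and at D3 in MCF7 (0, 115, 1), myricetin in the cardiomyocytes (3231, 2120, 396), 2-hydroxybenzophenone in MCF7 (3, 337, 46), the vehicle plates in the cardiomyocytes (0, 3150, 739) and avobenzone between cell types at D3 (52, 208, 0). The high counts for avobenzone D3, exchanged with vehicle alone, point to a structure of the samples as well.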
